A study of Homo sapiens with 8 samples.

How the data were processed

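Single-cell RNA sequencing was carried out on epithelial cells that had been grown in culture from 8 biopsies of 1 donor. Per the labels, 2 biopsies came from each of 4 sites: the central zone (CZ), the peripheral zone (PZ) and the transition zone (TZ) of the prostate, and the seminal vesicle (SV). Each biopsy was cultured separately in serum-free medium for basal epithelial cells, expanded, frozen and thawed before capture. The 8 libraries were made in 1 batch with the 10x Genomics 3' kit, version 3.1, with a target of 5000 cells per library.

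Per the submitters' processing notes, the authors used Cell Ranger 5.0.0 and GRCh38. The annotation release behind the gene names, and whether the libraries were equalised in depth when they were aggregated, are not given in the sources used here. The deposited matrix holds raw UMI counts (whole numbers, 1 count per distinct molecule) for 36648 genes in 47295 barcodes, with 1133721621 UMIs in all. The suffix of each barcode assigned it to its library, per the labels. The deposited aggregation sheet marks replicate 1 of every site with the word high and replicate 2 with the word low, in a column named density. What was dense is not stated. Gene coordinates were taken from GENCODE release 29, in which 34582 genes (94.4%) were matched by gene identifier without its version, and they are given on GRCh38.

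The rest was computed from those counts. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 40037 cells and removed 7258 barcodes. A doublet score called only 6 cells (0.015%) and was treated as not having worked, so no cells were removed as doublets. UMIs of the kept cells were summed per gene and library, and the library was the unit of every test between sites. The tests on free RNA run over barcodes and those on the order of HOX genes over genes. Differences between sites were tested with edgeR 4.0.16 (R 4.3.3), with TMM factors, the filterByExpr function for low counts (17937 genes tested) and the quasi-likelihood test on 4 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. The 4 groups of 2 libraries leave 4 residual degrees of freedom. Log2 fold changes carry the standard error (SE) of that fit. Levels are CPM with the standard deviation (SD) over libraries. CPM are UMIs of a gene per 1e6 UMIs of the tested genes in the library, scaled by its TMM factor. Levels within a cluster, or with and without a cluster, are instead per 1e6 UMIs of the pooled cells, without that factor. The p-values measure the spread among cultures of 1 donor, and that spread includes the density mark, so they say nothing about other donors. Intervals and lower bounds on folds for genes with 0 to 3 UMIs in a group cover counting error only. A lower bound sets the empty group to 3 UMIs.

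The comparisons were SV against the mean of the 3 zones, each pair of zones, SV against each zone, any difference among the 4 groups, and the 3 ways of joining the sites 2 by 2. The joins were fitted as 2 groups of 4 libraries and set beside all 35 splits of the 8 libraries into 4 and 4. For distances between sites, differences from 1 pair of libraries were multiplied by those from the other (log2 values with a prior count of 2). Noise that is independent between libraries then averages to 0, while an effect shared by same-numbered libraries need not. Gene lists written under 36 headings were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. A list of endothelial markers had no measured member. Clusters came from scanpy 1.11.5 with 2000 variable genes, 30 principal components, 20 neighbors and resolution 0.5 (leidenalg 0.10.2, seed 1). Clusters were named from marker lists, with the ending -like where the marker genes were the only ground, and left unnamed where their leading genes went against the name. Shares of cells per cluster were compared by an exact permutation test. The tests were repeated within non-cycling cells, meaning cells outside the clusters named cycling-like, which still include an unnamed cluster of zone cells with replication genes, and DESeq2 1.42.0 was run as a second tool. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

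The genes named were fixed by a rule before the data were examined: the 12 largest called changes each way for SV against the zones and for each pair of zones, and 5 each way for SV against single zones. They had to have a mean of at least 10 CPM in 1 of the groups, and every library of 1 side had to lie above every library of the other. Their separation of libraries was thus a condition and not a finding. Left out were, among others, mitochondrial and ribosomal protein genes and genes with clone, LINC or MIR host names. Up to 4 called members of each gene list and a panel of identity genes were added. The comparisons, gene lists and first set of alternatives were also fixed before the data were examined. Genes outside the rule are marked as chosen after their values were seen. Many genes that the rule named are not reported here.

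The depth of the kept cells ran from 68327440 to 198935793 UMIs per library. The pipeline was tested on simulated data drawn from these libraries, with 200 changed genes. Of simulated changes of 1 on the log2 scale, 80.6% were recovered for SV against the zones, 65.7% for CZ against PZ, 74.6% for CZ against TZ and 62.7% for PZ against TZ. Among all calls in those simulations, 19 of 181, 13 of 150, 18 of 162 and 7 of 146 were false, in the same order.

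Because the density mark pairs the libraries across sites, a fit with the replicate number as a block was planned. The deviations of same-numbered libraries from their site means correlated at 0.04 to 0.26 over the 6 pairs of sites. Other alternatives were RLE factors, DESeq2, no filter on low counts, all barcodes, a stricter cell filter (1500 genes, 10% mitochondrial UMIs), equal numbers of cells, thinned counts, only the 2 compared groups in the fit, called doublets removed, and each library left out in turn. Alternatives added after seeing the data were a depth window (cells of 10000 to 40000 UMIs with 2 to 12% mitochondrial UMIs), removal of the 6% of cells with the highest doublet scores, and SV against PZ and TZ without the CZ libraries, and the window, the stricter filter or the non-cycling cells jointly with the block. The counting is not stated to use strand and may split reads between near-identical copies. Antisense genes and members of the histone, SAA, SPRR, HLA, metallothionein and KRT81 families are therefore reported as uncertain.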

Results

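Messenger RNA was counted in single cells of 8 epithelial cultures, 2 from each of 4 sites of 1 donor: the CZ, PZ and TZ of the prostate and the SV, the gland that adjoins the prostate. The deposited libraries held 90198919 and 106773560 UMIs for CZ, 141906904 and 139545147 for PZ, 200442740 and 167841610 for TZ, and 141709535 and 145303206 for SV. After filtering, 9003 and 5877 CZ cells, 4820 and 4029 PZ cells, 6168 and 3615 TZ cells, and 3062 and 3463 SV cells remained. The CZ cells were shallow. Their median was 3053 UMIs in replicate 1 and 3842 in replicate 2, while the medians of the other 6 libraries ran from 20665 to 36849 UMIs. The median mitochondrial share of a CZ cell was 0.361% and 0.983%, and in the other libraries it ran from 6.65% to 8.47%. Cells under 4000 UMIs made up 58.1% and 50.8% of the kept CZ cells and held 17.3% and 7.51% of the CZ UMIs.

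**Figure D1:**
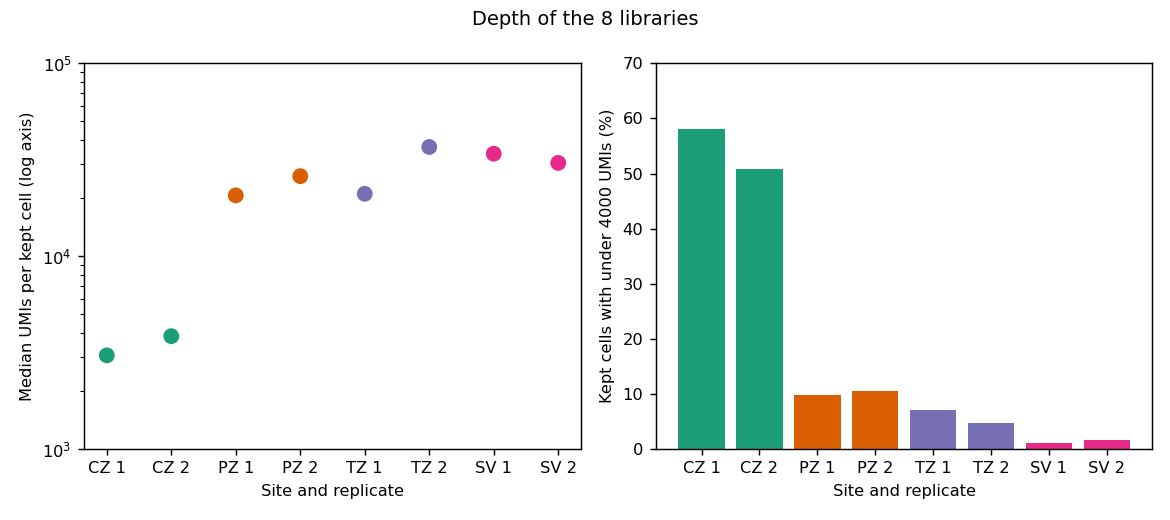
Median UMIs per kept cell (left, log axis) and the percentage of kept cells under 4000 UMIs (right) in each of the 8 libraries, coloured by site. The CZ medians lie at 3053 and 3842 UMIs and the others between 20665 and 36849, and 58.1% and 50.8% of CZ cells are under 4000 UMIs.

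The cultures expressed keratins of both basal and simple epithelia. KRT5 and KRT14, keratins of basal cells, averaged 2360 ± 212.7 and 3500 ± 527.1 CPM over the 6 zone libraries (SD, n = 6), and TP63, the basal transcription factor, averaged 20.4 ± 2.16 CPM. KRT19 and KRT7, keratins of simple epithelia, averaged 4264 ± 806.8 and 3184 ± 361.3 CPM there and 5604 ± 157.5 and 3596 ± 609.0 CPM in SV (n = 2). No UMI was found for SEMG1 or SEMG2, the secreted proteins of semen, for KLK3, the secreted protease of luminal prostate cells, or for DCN, a fibroblast marker. PTPRC, carried by leukocytes, had 4 UMIs in all.

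The first question was whether the sites differed at all. Across the 4 groups, 7717 of 17937 genes (43.0%) were called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). SV stood apart from the zones. The squared distance of log2 values, with independent noise averaged out by crossed pairs of libraries, averaged 1.21 ± 0.0233 from SV to a zone and 0.0854 ± 0.0123 between zones (SD over 6 values, 2 pairings of libraries for each of 3 pairs of sites), a ratio of 14.2. Between zones it was 0.0797 for CZ and PZ, 0.0846 for CZ and TZ, and 0.0918 for PZ and TZ. The first pairing gave the higher value for every pair of sites. In the same order, the zone values were 0.0882, 0.0900 and 0.106 in the first pairing and 0.0712, 0.0792 and 0.0776 in the second. The order of the zone distances is therefore not settled.

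SV cultures carried the transcription factors of the mesonephric duct, the embryonic structure from which the seminal vesicle forms, and had few or no UMIs of the HOX13 genes that the prostate cultures carried. PAX8 (ENSG00000125618.17, GRCh38 chromosome 2, 113215997 to 113278950) reached 97.1 ± 1.69 CPM in SV (SD, n = 2) against 0.119 ± 0.0809 in the zones (n = 6), a log2 fold change of 9.99 ± 0.12 (SE; adjusted p = 1.33e-15). LHX1 rose by 8.67 ± 0.13 and HOXB8 by 9.08 ± 0.13 on the log2 scale. EMX2 (ENSG00000170370.12, chromosome 10, 117542444 to 117549546) had 6779 UMIs in SV and 1 in the zones, a ratio of 19040 with a 95% counting interval of 3417 to 752300. POU3F3 had 3445 and 1 UMIs (ratio 9678, interval 1736 to 382400). PAX2 had 904 UMIs in SV and none in the zones and was at least 846.6-fold higher, and SIM1 with 1310 UMIs was at least 1227-fold higher. All 7 measured genes of the mesonephric duct list rose, over all genes and adjusted over the list alone (camera adjusted p = 1.19e-06; adjusted p = 0.157 with an estimated correlation).

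PRAC1 (ENSG00000159182.5, chromosome 17, 48721719 to 48722522), a gene beside HOXB13 that is expressed in the prostate and lower bowel, averaged 53.5 ± 14.1 CPM in the zones and had no UMI in SV, which puts it at least 4952-fold lower. Its neighbour PRAC2 had 15236 UMIs in the zones and 3 in SV (ratio 1808, interval 618.5 to 8767). SOX2, a progenitor transcription factor, had 11480 and 3 UMIs (ratio 1362, interval 466.0 to 6606). HOXB13, a transcription factor that marks the prostate, had 4459 UMIs in the zones and 1 in SV (ratio 1587, interval 284.7 to 62700). HOXA13 and HOXD13 had no UMI in SV and were at least 566.9-fold and at least 324.0-fold lower. HOXC13 was near the floor on both sides, with 62 UMIs in the zones and 6 in SV (log2 -1.77 ± 0.62, edgeR adjusted p = 0.0303). All 4 measured HOX13 paralogs fell, over all genes and adjusted over the list alone (camera adjusted p = 0.000223; adjusted p = 0.157 with an estimated correlation). Of 11 HOX8 to HOX11 paralogs, 6 rose and 5 fell, by both adjustments (camera adjusted p = 0.827), with HOXB8 among those that rose and HOXA11 (-9.65 ± 0.19), HOXA9 (-8.70 ± 0.15), HOXD11 (-7.87 ± 0.16) and HOXA10 (-7.03 ± 0.19) among those that fell. HOXD4 rose by 8.08 ± 0.12. EMX2OS (11.98 ± 0.17), LHX1-DT (8.70 ± 0.22) and HOXA10-AS (-8.53 ± 0.15) overlap or adjoin these genes, and reads may be shared between them.

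**Figure D2:**
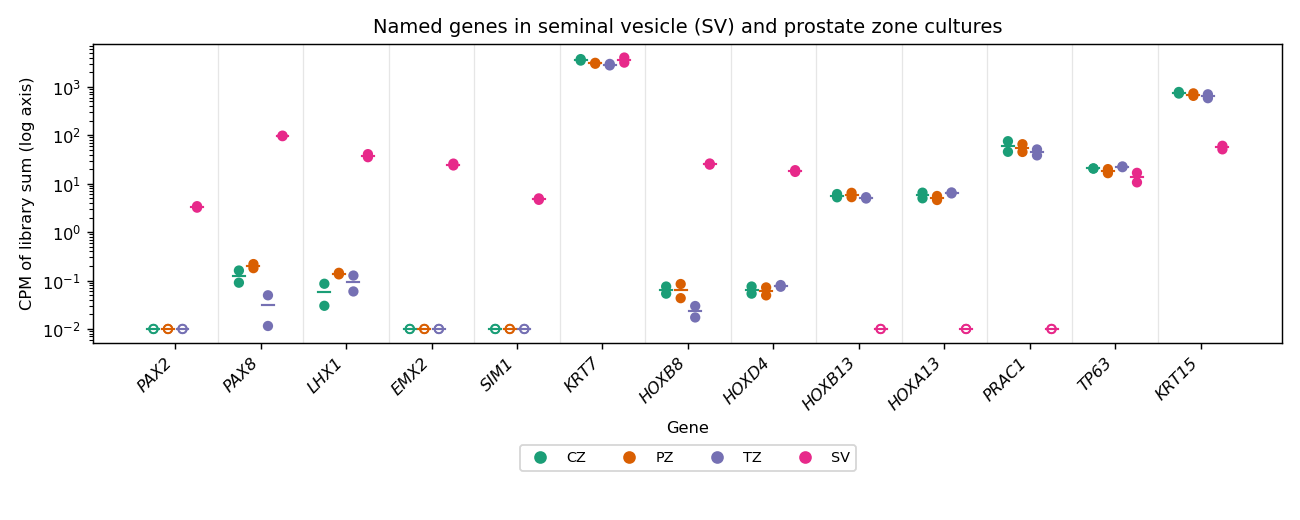
CPM of library sums (log axis) of named genes, with a point for each library, a line at the mean of each site's 2 libraries, colours for sites and open circles for values under 0.01 CPM, drawn at 0.01. PAX8 has a mean of 97.1 CPM in SV and 0.119 in the zones, and KRT15 of 55.95 and 696.7.

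**Figure D3:**
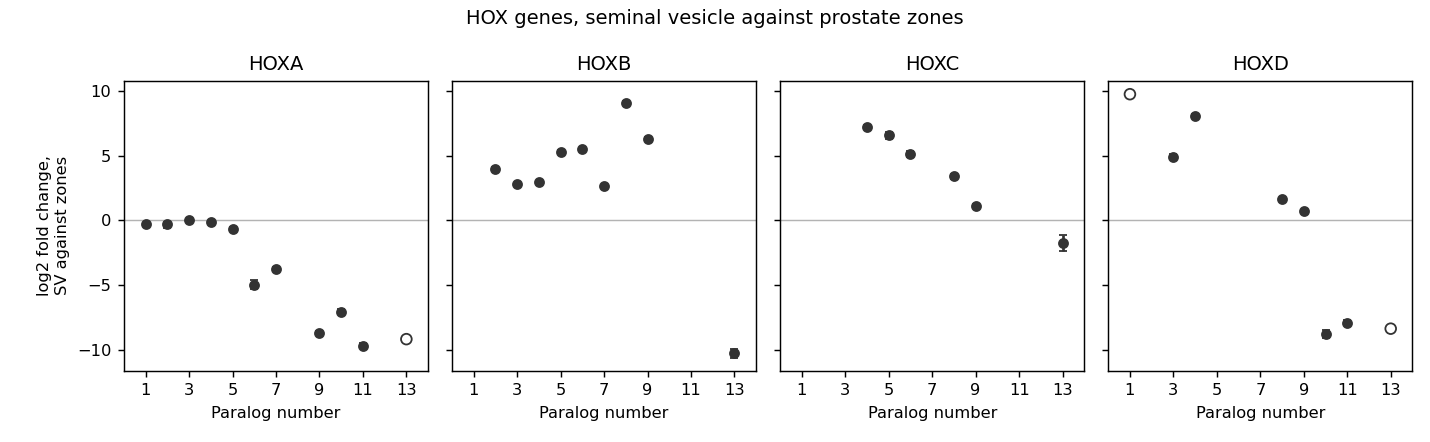
Log2 fold change of HOX genes in SV against the zones (vertical axis, bars of 1 SE) by paralog number (horizontal axis) in the 4 clusters, with open circles at the lower bound of genes without a UMI on 1 side. HOXB8 lies at 9.08 and HOXA11 at -9.65.

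The basal keratins KRT14, KRT15 and KRT5 were lower in SV cells, and most keratins of simple epithelia were higher. KRT17, another basal keratin, was near level, at 1767 CPM in SV and 1855, 1815 and 1869 CPM in CZ, PZ and TZ. KRT14 (ENSG00000186847.6, chromosome 17, 41582279 to 41586921) fell by 4.37 ± 0.12, KRT15 by 3.64 ± 0.12 and KRT5 by 1.00 ± 0.10 on the log2 scale (adjusted p = 1.1e-12, 5.33e-12 and 1.25e-06). KRT5 still averaged 1175 ± 200.1 CPM in SV. TP63 fell by 0.57 ± 0.13 (adjusted p = 0.00269), a call that was lost without SV replicate 2 (-0.28, adjusted p = 0.0692) and a change that grew to -0.93 without SV replicate 1. Of 13 basal and hemidesmosome genes, 10 fell and none rose, by both adjustments (camera adjusted p = 0.000223; adjusted p = 0.157 with an estimated correlation). KRT8, a keratin of simple epithelia, rose by 0.96 ± 0.07 and KRT23 by 5.17 ± 0.11, and 4 of 5 keratins of that list rose (camera adjusted p = 0.021; adjusted p = 0.547 with an estimated correlation). That list's call was lost without SV replicate 2 (adjusted p = 0.0672). KRT7 differed by 0.18 ± 0.09 and did not pass (adjusted p = 0.111). Of 17 squamous genes, 2 rose and 7 fell (camera adjusted p = 0.0924), with KRT6A, a keratin of stressed epithelium, at -4.22 ± 0.17.

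Other genes named by the rule follow, and none of the 3 lists of matrix genes was called. Of 12 metalloprotease and plasminogen genes 4 rose and 7 fell, of 10 basement membrane genes 1 rose and 4 fell, and of 13 mesenchymal genes 6 rose and 5 fell (camera adjusted p = 0.518, 0.166 and 0.68). FN1, fibronectin, averaged 4477 ± 341.6 CPM in SV and 124.0 ± 53.3 in the zones, a log2 fold change of 5.30 ± 0.13 (adjusted p = 3.43e-13). SERPINA1, a protease inhibitor, rose by 7.96 ± 0.18 and WFDC2, a secreted protein of the whey acidic type, by 7.14 ± 0.12. PLAT, the tissue plasminogen activator, rose by 4.52 ± 0.09, VIM by 1.32 ± 0.07, CALB2 by 7.14 ± 0.15, and SHISA9, with 3 UMIs in the zones, had a ratio of 4783 (interval 1636 to 23200). SLC14A1, a urea transporter, fell by 7.23 ± 0.11, MMP10 by 6.47 ± 0.23, MEG3 by 6.41 ± 0.16 and KRT81 by 6.69 ± 0.36.

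Among the lists of cell states, all 13 hypoxia and glycolysis genes rose by both adjustments (camera adjusted p = 3.75e-06; adjusted p = 0.387 with an estimated correlation). CA9, a carbonic anhydrase induced by low oxygen, rose by 5.25 ± 0.11 and PGK1, a glycolytic enzyme, by 1.11 ± 0.07. Of 12 p53 targets, 11 rose by both adjustments, with GDF15 at 3.52 ± 0.22 and BTG2 at 1.72 ± 0.09 (camera adjusted p = 0.000272; adjusted p = 0.387 with an estimated correlation). Of 18 NF-kB and cytokine genes, 13 rose and 3 fell, and 14 and 3 passed when adjusted over the list alone (camera adjusted p = 0.0028; adjusted p = 0.423 with an estimated correlation). LIF rose by 4.20 ± 0.14 and CXCL1 by 3.31 ± 0.22. Of 20 interferon-response genes, 3 rose and 13 fell, and 4 and 13 passed when adjusted over the list alone (camera adjusted p = 0.00254; adjusted p = 0.547 with an estimated correlation). IFI44L fell by 4.80 ± 0.21 while BST2 rose by 4.20 ± 0.15. Of 14 S phase genes 12 fell, and of 15 G2 and M phase genes 14 fell, by both adjustments (camera adjusted p = 0.000272 and 0.000195; adjusted p = 0.547 and 0.24 with an estimated correlation). CLSPN fell by 0.91 ± 0.10 and AURKA by 0.70 ± 0.07. In cells outside the cycling-like clusters, which in the zones still held a cluster of replication genes (DTL, E2F1, UHRF1, picked after their values were seen) without SV cells, the median change of the G2 and M phase list was -1.67 in place of -0.45, and that of the S phase list -1.13 in place of -0.69.

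In all, 4574 genes were higher and 4248 lower in SV than in the mean of the zones, of 17937 tested (49.2%), and 2799 of these differed at least 2-fold. Within non-cycling cells 4082 were higher and 3980 lower. None of the 10 called lists held with an estimated correlation. Against single zones, SV differed in 7641 genes from CZ, 7310 from PZ and 7405 from TZ. PAX8 was higher by 9.52 against CZ, 8.92 against PZ and 11.53 against TZ on the log2 scale, and SOX2 was lower by -10.19, -9.99 and -10.35. PRAC1, without a UMI in SV, was at least 5513-fold lower than in CZ, at least 5363-fold lower than in PZ and at least 4397-fold lower than in TZ. EMX2, without a UMI in CZ and TZ, was at least 1265-fold and at least 2902-fold higher in SV. IFNK, a keratinocyte interferon, had 3322 UMIs in PZ and none in SV and was at least 1147-fold lower there. The SV libraries correlated at 0.996 with each other and at 0.9449 to 0.9492 with the zone libraries (Pearson, log2 CPM). That argues against differences between single cultures as the whole cause. What both SV cultures had in common cannot be told apart from the site in 8 cultures of 1 donor. When SV against the zones was run on simulated data, 19 of 181 calls were false. Far fewer genes were changed in that simulation than were called here between SV and the zones. Its share of false calls therefore cannot be carried over to these calls, and their own share was not estimated.

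The zones were compared next, to see whether cultures kept differences between parts of the prostate. The basal keratins KRT5 and KRT14 were not called between zones. KRT5 differed by 0.00 ± 0.11 between CZ and PZ, by -0.21 ± 0.11 between CZ and TZ, and by -0.21 ± 0.11 between PZ and TZ, and none passed (adjusted p = 1.0, 0.461 and 0.604). KRT14 differed by -0.28 ± 0.11, -0.42 ± 0.11 and -0.14 ± 0.11 in the same order (adjusted p = 0.26, 0.0821 and 0.816), and between CZ and TZ it was called with the replicate block (-0.42, adjusted p = 0.0497).

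CZ cultures expressed more MMP10 and PPARG than PZ cultures and less SAA1 and TNFRSF6B. MMP10 (ENSG00000166670.10, chromosome 11, 102770503 to 102780628), a stromelysin, reached 33.1 ± 2.47 CPM in CZ and 4.49 ± 0.960 in PZ (SD, n = 2 each), a log2 fold change of 2.88 ± 0.16 (SE; adjusted p = 5.78e-07). PPARG (ENSG00000132170.22, chromosome 3, 12287368 to 12434356), the nuclear receptor of fat metabolism, was higher by 1.35 ± 0.13 (adjusted p = 0.000102). LCP1, an actin bundler, was higher by 1.37 ± 0.18, IGFBP2 by 1.01 ± 0.13 and GJB2, a gap junction protein, by 0.95 ± 0.09. The collagenase MMP1 was higher by 1.72 ± 0.28 (adjusted p = 0.00487; without CZ replicate 2, 1.32 and adjusted p = 0.0657). FABP4, a fatty acid carrier and PPARG target, was higher by 1.92 ± 0.35 (adjusted p = 0.0105), a call lost without CZ replicate 2 (adjusted p = 0.104) and with DESeq2 (adjusted p = 0.529).

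SAA1, an acute-phase protein, fell from 31.1 ± 1.21 CPM in PZ to 12.0 ± 0.264 in CZ (-1.38 ± 0.15, adjusted p = 0.000295), and its reads may be shared with SAA2. TNFRSF6B (ENSG00000243509.6, chromosome 20, 63696651 to 63698684), a decoy receptor for death ligands, was lower in CZ by -1.29 ± 0.10 (adjusted p = 1.4e-05). COL8A1 was lower by -1.06 ± 0.13, KLK5 by -1.05 ± 0.10, LY6K by -0.96 ± 0.09, CALML3 by -0.94 ± 0.11, the axon-guidance ligand SLIT2 by -0.94 ± 0.10, the Wnt antagonist SFRP1 by -0.71 ± 0.09 and RAB3B by -0.71 ± 0.11. KRT23 was lower by -1.76 ± 0.18. The rule also named genes whose calls were lost without 1 library. KRT81 (1.10), H2AC16 (1.07), H3C4 (1.02), TENM2 (-1.04) and HOXA7 (-0.78) lost theirs without CZ replicate 1, POU2F2 (-0.79) lost its call without PZ replicate 1, and the first 3 of these belong to families with similar sequences.

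For some squamous genes that were higher in CZ, a few cells held a large part of the UMIs. KRT13, a keratin of squamous and hillock cells, was higher by 5.64 ± 0.60 (adjusted p = 0.000167), and 77.4% of its CZ UMIs lay in 1 cluster of 95 cells. That cluster had a median of only 3791 UMIs and 0.263% mitochondrial UMIs. Without it KRT13 stood at 1.94 CPM in CZ and 0.109 in PZ. The log2 fold change was 3.01 in the depth window. CRCT1, a cornified-envelope gene, was higher by 5.68 ± 1.17 (adjusted p = 0.0228), and 3140 of its 3296 CZ UMIs lay in 1 barcode. Its call was lost in the depth window (0.56) and without CZ replicate 2 (1.08). S100A9, a subunit of calprotectin, was higher by 1.67 ± 0.22 (0.95 in the depth window, still called), with 41.6% of its CZ UMIs in that cluster and 3652 of 13355 in 1 barcode. IVL, involucrin, was higher by 3.82 ± 0.33, and without that cluster it stood at 1.24 CPM in CZ and 0.128 in PZ.

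Of 17 squamous genes, 3 rose and 1 fell, and 5 and 1 passed when adjusted over the list alone (camera adjusted p = 0.0128; adjusted p = 0.501 with an estimated correlation). That call was lost in the depth window, where the median change was 0.05 in place of 0.78 (adjusted p = 0.517), and without CZ replicate 2 (0.18, adjusted p = 0.356). Of 8 club and secretory genes, 2 rose (6 adjusted over the list alone; camera adjusted p = 8.83e-05; adjusted p = 0.39 with an estimated correlation), with a median of 1.48 and of 0.49 in the depth window. CXCL17, of that list, was higher by 2.88 ± 0.34 and lost its call in the window (0.79). Of 5 hillock genes, 2 rose (4 adjusted over the list alone; camera adjusted p = 0.00226; adjusted p = 0.39 with an estimated correlation), and this call too was lost in the window (adjusted p = 0.0756). Of 10 basement membrane genes, 2 rose (8 adjusted over the list alone; camera adjusted p = 8.83e-05; adjusted p = 0.311 with an estimated correlation). These were NID1 (0.63 ± 0.13) and COL4A1 (0.49 ± 0.11), each lost without PZ replicate 1. Of 12 metalloprotease and plasminogen genes, 3 rose (4 adjusted over the list alone), and of 13 mesenchymal genes 3 rose by both adjustments (camera adjusted p = 0.00321 and 0.00873; adjusted p = 0.501 with an estimated correlation for both). Both calls were lost without PZ replicate 1. Among the mesenchymal genes, TGFBI was higher by 0.94 ± 0.13.

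Further lists were called between CZ and PZ with few members past the test. Of 10 stem-associated genes 2 rose, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0182; adjusted p = 0.39 with an estimated correlation). Of 18 NF-kB genes 1 fell, with 1 up and 5 down when adjusted over the list alone (camera adjusted p = 0.0282, and 0.0506 with the replicate block). Of 7 metallothioneins 1 fell, MT1M at -1.66 ± 0.23, and 2 fell when adjusted over the list alone (camera adjusted p = 0.0146; adjusted p = 0.667 with an estimated correlation). No member passed over all genes in the stress-response list (camera adjusted p = 0.0282, lower; 3 fell adjusted over the list alone), the fibroblast list (0.0282, higher; 2 rose) or the G2 and M phase list (0.0282, lower), and with an estimated correlation the adjusted p was 0.694, 0.501 and 0.501, and 0.501 for NF-kB. The stem, NF-kB, metallothionein, stress-response and G2 and M phase calls were each lost without CZ replicate 2 (adjusted p from 0.0667 to 0.583), and the fibroblast call without CZ replicate 1. The G2 and M phase median turned from -0.13 to 0.36 in cells outside the cycling-like clusters, which still held a cluster of replication genes.

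CZ exceeded PZ in 182 genes and fell below it in 157 (339 of 17937, 1.89%), and 166 of these differed at least 2-fold. The replicate block raised the total to 613. Without CZ replicate 1 it was 161, and within cells of the depth window 203. The CZ libraries held 56.2 ± 9.62% of their cells in a cluster of few UMIs that made up 2.64 ± 1.53% of PZ cells.

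CZ cultures expressed more FN1 than TZ cultures and less KRT23 and MIA. FN1 (ENSG00000115414.20, chromosome 2, 215360440 to 215436172) averaged 174.2 ± 8.00 CPM in CZ and 63.3 ± 16.9 in TZ, a log2 fold change of 1.46 ± 0.18 (SE, n = 2 each; adjusted p = 0.000473). FN1 was also the top gene (1389 CPM) of a cluster of 1098 zone cells with a median of 15.1% mitochondrial UMIs, which held 6.16% of CZ, 0.872% of PZ and 0.446% of TZ cells, and MMP10, APOE, TGFBI and COL1A1 were higher in that cluster too. The change of FN1 was 1.02 with the stricter cell filter (adjusted p = 0.0152) and 1.32 in the depth window (still called), in which 111 of 973 CZ cells of that cluster stayed, while APOE (0.91, adjusted p = 0.243) and COL1A1 (0.59, adjusted p = 0.0649) lost their calls with that filter. CDKN2A, a cell cycle inhibitor, was higher in CZ by 1.05 ± 0.13, SAA1 by 1.12 ± 0.16, HOXB7 by 0.89 ± 0.09 and MX1, an antiviral protein, by 0.86 ± 0.12. KRT23 (ENSG00000108244.17, chromosome 17, 40922696 to 40937634) was lower in CZ by -2.53 ± 0.18 (adjusted p = 3.32e-06), and MIA (ENSG00000261857.7, chromosome 19, 40771648 to 40777490), a secreted cartilage and melanoma protein, by -1.57 ± 0.14 (adjusted p = 3.25e-05). ITM2A was lower by -1.12 ± 0.16, SFRP1 by -1.05 ± 0.09, the lipid droplet protein PLIN2 by -0.93 ± 0.11, LY6K by -0.86 ± 0.09, CALML3 by -0.85 ± 0.11 and CLMP by -0.76 ± 0.12. ALDH1A1, which makes retinoic acid, was lower by -1.92 ± 0.17.

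Genes named by the rule whose calls were lost without CZ replicate 1 were APOE (1.24), SMIM22 (0.95), NIBAN1 (-0.66), ANPEP (-0.59) and the histone genes H2AC16 (1.32), H3C4 (1.30), H3C2 (0.95) and H1-1 (-0.72). Those of S100A9, higher in CZ, and KLK10 (0.83) were lost without CZ replicate 2. S100A9 was also lost in the depth window (0.44). H1-1 changed direction, to 0.53, in cells outside the cycling-like clusters.

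Of 20 interferon-response genes, 7 rose in CZ over TZ and 16 when adjusted over the list alone (camera adjusted p = 7.32e-10; adjusted p = 0.419 with an estimated correlation). The median was 0.56, and 0.54 in the depth window (still called), which holds 5 of the 8572 CZ cells of the few-UMI cluster, where the interferon markers IFIT1, IFIT3, ISG15 and OAS1 were higher than in other cells. Of 8 club and secretory genes 4 rose, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000284; adjusted p = 0.419 with an estimated correlation), with a median of 1.66 and of 0.80 in the depth window. They included MMP7 (2.94 ± 0.43, lost without CZ replicate 2) and CXCL17 (2.89 ± 0.33, lost in the depth window). Of 5 hillock genes 2 rose (4 adjusted over the list alone; camera adjusted p = 0.00514), of 18 NF-kB genes 2 rose (3 adjusted over the list alone; 0.000769), of 4 fibroblast genes 2 rose (3 adjusted over the list alone; 0.000769) and of 7 retinoid-response genes 1 rose, TGM2 at 0.63 ± 0.08 (5 adjusted over the list alone; 0.000769). With an estimated correlation the adjusted p was 0.419 for each. In the depth window these 4 calls were lost (adjusted p = 0.281, 0.167, 0.167 and 0.0649). The fibroblast genes were COL1A1 (0.80 ± 0.13) and FBLN1 (0.46 ± 0.10), both lost without CZ replicate 1. The basement membrane list passed with no member called over all genes (camera adjusted p = 0.046; adjusted p = 0.419 with an estimated correlation) and had a median of 0.00 under the stricter cell filter (adjusted p = 0.958). HOX8 to HOX11 paralogs moved both ways, 2 up and 3 down over all genes and 4 up and 5 down adjusted over the list alone (camera adjusted p = 0.874), and HOXB9 was higher by 2.00 ± 0.28.

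CZ exceeded TZ in 225 genes and fell below it in 102 (327 of 17937, 1.82%), 183 of them at least 2-fold. The replicate block raised the total to 507. It was 155 without CZ replicate 1 and 177 in the depth window, and the few-UMI cluster held 0.437 ± 0.0701% of TZ cells.

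PZ cultures expressed more SAA1 and TNFRSF6B than TZ cultures, and TZ cultures more MMP10, PPARG and PLIN2. SAA1 (ENSG00000173432.12, chromosome 11, 18266174 to 18269977) averaged 31.1 ± 1.21 CPM in PZ and 5.52 ± 0.415 in TZ (log2 2.50 ± 0.16 SE, n = 2 each; adjusted p = 4.59e-07). TNFRSF6B was higher in PZ by 1.52 ± 0.10 (adjusted p = 7.84e-07), the transcription cofactor EYA2 by 1.46 ± 0.10 (1.22e-06), TENM2 by 1.54 ± 0.17, KLK10 by 1.11 ± 0.16, FN1 by 1.09 ± 0.17 (not called with only those groups in the fit, adjusted p = 0.0523), MX1 by 1.06 ± 0.12, COL8A1 by 1.00 ± 0.13, HOXB7 by 0.96 ± 0.09 and SLC43A3 by 0.95 ± 0.11. In the other direction, MMP10 was lower in PZ by -2.63 ± 0.16 (adjusted p = 3.91e-07), MMP1 by -1.75 ± 0.28, PPARG by -1.63 ± 0.13 (4.63e-06), PLIN2 by -1.68 ± 0.11 (8.48e-07) and FABP4 by -2.75 ± 0.35 (0.000347; 0.254 with DESeq2). ENG, a TGF-beta co-receptor, was lower by -1.22 ± 0.10, MIA by -1.08 ± 0.14, PPP1R14A by -0.98 ± 0.14, C4orf19 by -0.94 ± 0.09 and the growth factor EREG by -0.88 ± 0.09. ALDH1A1 was lower by -3.34 ± 0.18 (adjusted p = 1.13e-07).

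The rule also named KRT16, higher by 1.11 with a call lost without PZ replicate 1, KRT81 at -1.94 ± 0.26, SPRR1B at -3.69 ± 0.66, and the antisense gene APCDD1L-DT at 1.14 ± 0.17. Of the TZ UMIs of SPRR1B, 79.5% lay in the cluster of 95 cells and 1707 of 4636 in 1 barcode, and its value was -2.34 in the depth window.

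**Figure D4:**
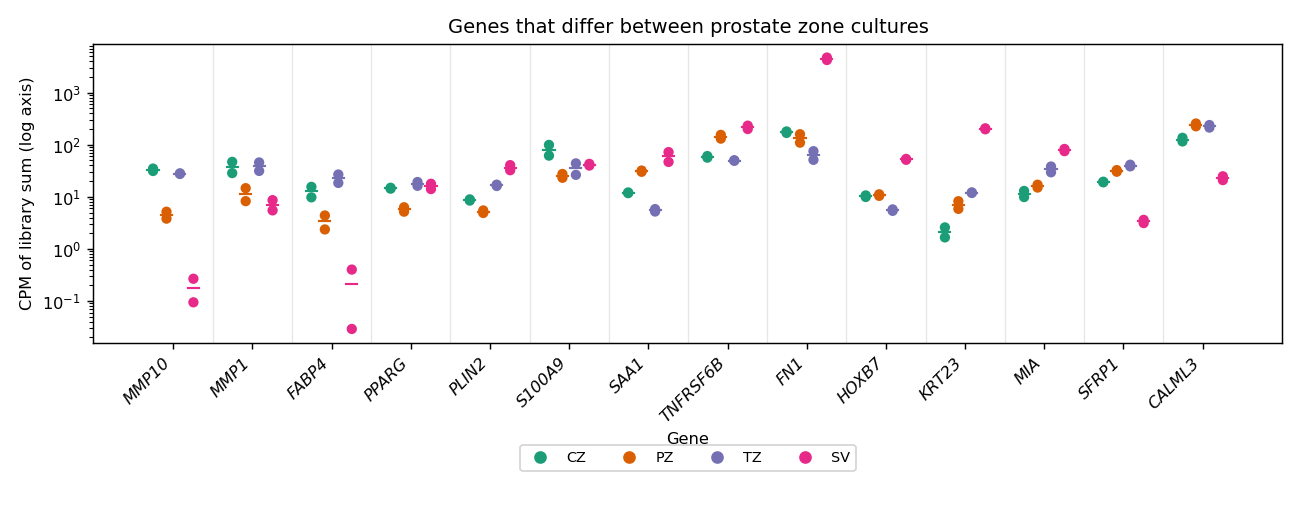
CPM of library sums (log axis) of genes named between zones, with a point for each library, a line at the mean of each site's 2 libraries and SV shown beside the zones. SAA1 has means of 12.0, 31.1 and 5.52 CPM in CZ, PZ and TZ, and MMP10 of 33.1, 4.49 and 27.9.

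Of 20 interferon-response genes, 12 rose in PZ over TZ and 14 when adjusted over the list alone (camera adjusted p = 3.27e-12; adjusted p = 0.405 with an estimated correlation). XAF1 was higher by 1.73 ± 0.17 and IFI44 by 1.02 ± 0.14. Of 18 NF-kB and cytokine genes, 6 rose and 10 when adjusted over the list alone (camera adjusted p = 4.32e-08; adjusted p = 0.405 with an estimated correlation). Its median of 0.72 became 1.10 without PZ replicate 1 and 0.30 without PZ replicate 2. Of 7 metallothioneins, 3 rose and 5 when adjusted over the list alone (camera adjusted p = 2.34e-05; adjusted p = 0.529 with an estimated correlation), with MT1M at 2.40 ± 0.22. The median of that list was 0.39, and 0.15 without PZ replicate 1. Of 10 MHC genes 2 rose by both adjustments, CD74 at 0.77 ± 0.10 among them (camera adjusted p = 0.0101; adjusted p = 0.444 with an estimated correlation), a call lost without PZ replicate 2. Of 7 retinoid-response genes 2 rose, TGM2 at 0.93 ± 0.08 among them (camera adjusted p = 0.0241, and 0.0782 with the replicate block; adjusted p = 0.405 with an estimated correlation), and the list's median of 0.46 was 0.16 without PZ replicate 2. Of 12 metalloprotease and plasminogen genes 2 fell, with 1 up and 4 down when adjusted over the list alone (camera adjusted p = 0.0177; adjusted p = 0.672 with an estimated correlation), a call lost without PZ replicate 1. Of 10 basement membrane genes 1 fell (camera adjusted p = 0.0304; adjusted p = 0.405 with an estimated correlation), a call lost without PZ replicate 2. The stress-response list passed with no member called (camera adjusted p = 0.0305; adjusted p = 0.672 with an estimated correlation), and its median turned from 0.23 to -0.02 without PZ replicate 1. PAX8, the only measured gene of the SV secretory list, had 56 UMIs in PZ and 12 in TZ (2.61, not called in the depth window; camera adjusted p = 0.0328, and 0.0745 with the replicate block; adjusted p = 0.405 with an estimated correlation). Of 17 squamous genes 1 rose and 3 fell, with IVL at -3.75 ± 0.32 (camera adjusted p = 0.119).

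PZ exceeded TZ in 353 genes and fell below it in 218 (571 of 17937, 3.18%), 283 of them at least 2-fold. Within non-cycling cells the total was 351, with 222 higher and 129 lower. For CZ against PZ and CZ against TZ the totals within non-cycling cells were 220 (398 with the replicate block) and 251.

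The sites were also joined 2 by 2, and few genes were called among the 16947 tested. Each join was fitted as 2 groups of 4 libraries, so both libraries of a site counted as replicates. Each side holds only 2 sites, and these p-values can overstate the evidence for a join. With CZ and SV set against PZ and TZ, 2 genes passed, named here after their values were seen. IRX4 (ENSG00000113430.10, chromosome 5, 1877413 to 1887236), a homeobox transcription factor, stood at 6.77 and 6.37 CPM in PZ and 6.67 and 6.32 in TZ, against 0.527 and 0.483 in CZ and 0.566 and 0.7502 in SV (-3.48 ± 0.15, adjusted p = 0.000124). TDRD12, a gene of the germline piRNA pathway, was higher by 6.15 ± 0.48 (adjusted p = 0.00733), at 0.587 and 0.515 CPM in CZ and 1.02 and 0.683 in SV. With CZ and TZ set against PZ and SV, 6 passed: AC008555.4 (1.18 ± 0.13), SLIT2 (-0.88 ± 0.07), BCL2A1 (-1.47 ± 0.15), TNFRSF6B (-1.73 ± 0.18), APLN (-2.63 ± 0.25) and PIWIL2 (-3.52 ± 0.41), with adjusted p from 0.0119 to 0.0496 (chosen after their values were seen). None passed with the replicate block. With CZ and PZ set against TZ and SV, no gene passed with edgeR, although 2437 had p under 0.05, and DESeq2 called 326. DESeq2 called 599 and 519 in the other joins.

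The cells formed 12 clusters of at least 20 cells, and 2 cells lay outside them. SV cells lay almost wholly in 3 clusters of their own, a cluster with 56.1 ± 2.55% of SV cells (SD, n = 2), in which the basal markers COL17A1, ITGB4 and LAMA3 were higher than in other SV cells but not among the 10 leading genes, and a pair of cycling-like clusters with 28.4 ± 0.738% and 15.4 ± 1.80%. Cells of all 3 zones and no SV cell were found in 3 cycling-like clusters and 3 unnamed clusters. The smallest p that the pairings of libraries allow is 0.009524, and among the zones alone it is 0.06667, so shares cannot reach 0.05 between zones. The exact permutation test over the 4 sites passed for 8 of 12 clusters (adjusted p = 0.02857). It passed for 0 of 9 at resolution 0.3 and for 2 of 8 after thinning. Of the 8 that passed in the main setting, 6 hold no SV cell. The 3 clusters of SV cells alone did not pass (exact permutation p = 0.1429), so SV cells clustering apart is not enough for a pass. How the zone libraries pair matters too, but among the zones alone the p of those 8 was 0.06667 or 0.1333. The test is therefore not read as a difference in shares. Shares are described, not compared. The few-UMI cluster, with 8845 cells and a median of 2134 UMIs and 0.234% mitochondrial UMIs, held 63.0% and 49.4% of CZ cells. The unnamed cluster of 1098 zone cells, with a median of 15.1% mitochondrial UMIs and matrix genes such as FN1 and MMP10 in the lead, held 7.95% and 4.37% of CZ cells and less than that of each other library. Cycling-like clusters held 19.4 ± 7.79% of CZ, 50.3 ± 4.90% of PZ, 54.3 ± 1.80% of TZ and 43.8 ± 2.54% of SV cells. The low CZ share is counted over all kept cells, the few-UMI cluster included. Among cells of the depth window the shares were 53.1 ± 4.24%, 55.7 ± 4.22%, 57.3 ± 0.34% and 45.8 ± 4.01%, in the same order. These shares are not compared, since an unnamed cluster whose top genes act in DNA replication (DTL, E2F1, UHRF1, picked after their values were seen) held a further 10.6 ± 0.960% of CZ, 24.8 ± 0.236% of PZ and 22.8 ± 2.26% of TZ cells and no SV cell. Free RNA from other cells was left open as a source of such calls.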

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

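All tests of explanations in this part were chosen after the results were seen: the tests on free RNA, on nuclear and mitochondrial RNA, on cells of the depth window and on the splits by density.

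No comparison of the report set the libraries marked low against those marked high, although the mark coincides with the replicate number of the block, and a signal appeared in it. Between the 4 libraries marked low and the 4 marked high, with site in the fit, 102 genes differed (edgeR quasi-likelihood test, 41 higher and 61 lower in low). Libraries marked low had more of the proteases MMP1 (log2 0.68 ± 0.06 SE, adjusted p = 0.00086) and MMP9 (0.79 ± 0.08), of the hyaluronan synthase HAS2 (0.58 ± 0.06) and of PAPPA (0.89 ± 0.10). They had less of HERPUD1 (-0.47) and DERL3 (-0.45), which act in the clearing of misfolded proteins, of NGFR (-0.68), RAMP1 (-0.61) and EGR1 (-0.52), and of the clock genes PER1 (-0.40) and DBP (-0.48). Each of these genes moved the same way at 4 of 4 sites, and they were picked after their values were seen. Of 12 stress-response genes 3 fell, and of 12 metalloprotease and plasminogen genes 2 rose (camera adjusted p = 0.000189 and 0.00121; adjusted p = 0.63 with an estimated correlation for both). The S phase list was higher with no gene called (camera adjusted p = 0.000597; adjusted p = 0.63 with an estimated correlation). In all 9 of 35 lists passed, the other 6 (metallothioneins, fibroblast and p53 lists lower, hypoxia, heat shock and NRF2 lists higher) at camera adjusted p = 0.0215 to 0.0498, and with an estimated correlation (adjusted p = 0.63 to 0.654) none did.

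Shallow and damaged barcodes as the whole cause of these 102 differences are argued against by cells of the depth window (10000 to 40000 UMIs, 2 to 12% mitochondrial). There the median ratio of the changes to the reported ones was 1.0 (quartiles 0.922 and 1.11), with 99 of 99 tested genes in the same direction and 78 still called. In that window 174 genes were called in all. Cells under 4000 UMIs held 0.0572% to 0.683% of the UMIs of the PZ, TZ and SV libraries. Losing them therefore left the ratio little room to fall there. Within non-cycling cells 33 genes were called, while 102 of 102 kept the direction with a median ratio of 1.01. The density marks give 8 splits that keep the pairs, too few for a share under 0.05: 1 of 8, the real one, gave as many genes, with 102 against 7 in the highest of the others. What stays open is a response of the cells to crowding or to some other difference between replicate 1 and replicate 2 that the sheet does not describe, which may include handling, and neither was tested.

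On average 56.2% of CZ cells formed a cluster with few UMIs and few mitochondrial UMIs. Free RNA in droplets without a cell could give shallow barcodes. As the whole cause it is argued against by the G2 and M phase UMIs. Their variance exceeded the mean by a ratio of 1.633 in CZ replicate 1 and 1.925 in replicate 2. Both lie above the highest of 1000 simulations of free RNA (1.06 and 1.10). The ratio was higher, however, in PZ barcodes of the same cluster (2.805 and 3.878). It was also higher in a further cluster with a median of 1764 UMIs (2.353 to 3.38 over the 6 zone libraries). Free RNA as a part of the cause stays open. Damaged cells that lost nucleus and mitochondria would be short of nuclear RNAs, and these stood at a median log2 difference of -2.19 and -2.28 from intact cells of the CZ libraries. The few mitochondrial UMIs defined the pattern and test nothing. In 75 and 150 PZ barcodes of the same cluster nuclear RNAs stood at a median of -2.77 and -2.05, and mitochondrial RNAs at -0.18 and -0.55. Some nuclear RNAs were at the floor: KCNQ1OT1 and SNHG14 had no UMI in PZ replicate 1, nor MEG3 in replicate 2. MALAT1, the most abundant nuclear RNA of the list, stood at -1.11 and -0.81. Nuclear RNAs were thus short there with little loss of mitochondrial RNAs, but the medians may overstate by how much. The PZ and CZ barcodes differed in this trait, since the mitochondrial medians of the CZ barcodes were -3.78 and -3.51. Whether they are otherwise the same kind cannot be told. Profiles of the cluster correlated at 0.368 to 0.552 between CZ and PZ libraries and at 0.962 between the CZ libraries. The PZ libraries correlated at only 0.428 with each other, so a low value between CZ and PZ decides nothing. The nuclear values of CZ are in line with damage of cells before capture, a candidate explanation found and tested on the same data, but they do not show that nucleus and mitochondria were lost together. Whether free RNA would be short of nuclear RNAs as well was not tested, so the nuclear values do not tell it from damage. Whether such damage belongs to the site or to the culture and thawing of both CZ biopsies was not tested either.

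Damaged barcodes in CZ could also produce the gene differences between CZ and the other zones. As the whole cause they are argued against by cells of the depth window, which holds 5 of the 8572 CZ cells of the few-UMI cluster: the median ratio of the changes to the reported ones was 0.952 for CZ against PZ (quartiles 0.830 and 1.05) and 0.940 for CZ against TZ. Of the 339 and 327 genes, 171 and 155 were still called, and 313 of 315 and 297 of 298 that could be tested there had the same direction. Cells under 4000 UMIs held 17.3% and 7.51% of the CZ UMIs, so the reported sums already rested mostly on deeper cells. The ratio had limited room to fall for that reason. The window bounds depth and does not equalise it, with a mean of 19730 and 22709 UMIs per cell in CZ, 21749 and 24234 in PZ, and 21630 and 25314 in TZ. It also keeps 111 of the 973 CZ cells of a cluster with many mitochondrial UMIs. Several lists lost their calls there: the squamous and hillock lists for CZ against PZ, and the hillock, NF-kB, fibroblast, retinoid and basement membrane lists for CZ against TZ, which left 2 of 7. A difference between the zones themselves stays open and untested beyond this donor.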

How the results depend on the processing

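The alternatives added after seeing the data, and so chosen once results were seen, were the depth window, the removal of the highest doublet scores, SV without the CZ libraries, and the joint settings. SV against the zones or a single zone, and the difference among the 4 groups, stayed within 1.5 times under the alternatives run. The count for SV against the zones ran from 7051 to 9452, and from 6506 to 9093 with 1 library left out. Left out, a library leaves a group with 1, which is then assumed to vary like the others. Depth limits genes at a low level: MMP7, called between CZ and TZ, had 54 and 16 UMIs there.

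The zone counts moved more, and the cause was not tested unless the setting itself shows it. CZ against PZ gave 1027 genes with no filter on low counts, 1119 with all barcodes, 222 with the stricter filter, 613 with the replicate block, 220 in non-cycling cells, 203 in the depth window, and 161 to 504 with 1 library left out. CZ against TZ gave 941, 1397 with all barcodes, 202 with equal cells, 507 with the block, 177 in the window and 155 to 437. PZ against TZ gave 1034 with no filter and 351 in non-cycling cells (383 to 654 with 1 library left out). In non-cycling cells, CZ against PZ gave 868 with no filter, 145 with the stricter filter, 107 with equal cells, 398 with the block, 145 in the window and 81 to 308. CZ against TZ gave 798, 126, 112 with equal cells, 111 in the window and 96 to 287. PZ against TZ gave 742 and 202 to 386.

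For the joins, DESeq2 called 599, 519 and 326. CZ and SV against PZ and TZ gave 1 in the window with the block and 1 to 3 with 1 library left out. CZ and TZ against PZ and SV gave 0 with the block, 3 in the window, 1 with the stricter filter and block, 0 with the window and block, and 0 to 9 with 1 library left out.

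With an estimated correlation 0 lists were called in each of the 4 comparisons. With 1 library left out, 5 to 12 were called for CZ against PZ and 5 to 8 for PZ against TZ. CZ against TZ had 11 with all barcodes, 2 in the window and 4 in the window with the block. The G2 and M phase list for CZ against PZ reversed to 0.36 in non-cycling cells (0.35 with the block), and the stress-response list for PZ against TZ to -0.02 without PZ replicate 1 (-0.02 to 0.39 with 1 library left out). H1-1 for CZ against TZ reversed to 0.53 and 0.55 in the same settings, and PSCA for SV against CZ to 0.34 in the window (0.34 with the block) and 0.15 without CZ replicate 1 (-2.05 to 0.15 with 1 library left out). The distance from SV to a zone was 0.885 with no filter, 1.151 with equal cells, 1.07 thinned, 1.142 in non-cycling cells, 0.984 in the window, 1.54 with prior count 0.5 and 1.174 to 1.219 with 1 library left out. Between zones it was 0.0700, 0.114 with all barcodes, 0.0711 thinned, 0.0534 in the window and 0.111 with prior count 0.5. Clusters that passed the test on shares were 0 at resolution 0.3 and 2 after thinning.

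Apart from the estimated correlation, which ended all list calls, 16 of the 38 called lists kept their call under every setting run, as did 188 of 213 named genes for SV and 71 of 149 between zones. Besides the block values given beside the results, the block weakened no other named call. It added calls for KRT19 (0.46) and KRT14 (-0.42) between CZ and TZ, for TP53I3, HERPUD1, DHRS3 and COL1A1 between CZ and PZ, and for HERPUD1 and COL1A1 between PZ and TZ, and it changed no other call.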

Other observations

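A cluster of 95 cells, not compared in the report, carried 8 squamous markers and 5 hillock markers. Its median of 3791 UMIs and 0.263% mitochondrial UMIs was low, as in the few-UMI cluster (2134 and 0.234%). The cluster of 95 cells made up 0.400% and 0.698% of CZ cells and at most 0.130% of any other library (exact permutation p = 0.06667, adjusted p = 0.08889, which does not pass). Most CZ UMIs of the antiprotease genes PI3 (94.4%) and SLPI (83.6%), both picked after their values were seen, and 49.7% of those of IVL lay in it, but 1 barcode alone held 1227 of 1382 PI3 UMIs and 2915 of 4670 SLPI UMIs. Without it, KRT13 in CZ fell from 8.56 to 1.94 CPM and CRCT1 from 20.7 to 0.643 CPM.

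A pair of retinoid genes moved in opposite directions between TZ and the other zones. ALDH1A1 averaged 1.11 CPM in CZ, 0.409 in PZ and 4.17 in TZ, while TGM2, induced by retinoic acid, averaged 84.2, 103.2 and 54.4 CPM. In SV, ALDH1A1 rose by 3.83 and TGM2 by 2.37 on the log2 scale over the zones.

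The tests below were all chosen after the results were seen: those on the order of the HOX genes, and the splits of the 8 libraries as they are read here. One hypothesis was that position along a HOX cluster orders the difference between SV and the zones, with anterior genes higher in SV and posterior genes lower. Across genes, which are not independent replicates, Spearman's rho of HOX number with the log2 fold change was -0.91 in HOXA (11 genes, permutation p = 0.00027, adjusted p = 0.00108), -1.0 in HOXC (6 genes, exact p = 0.002778, adjusted p = 0.003704) and -0.95 in HOXD (8 genes, exact p = 0.001141, adjusted p = 0.002282). In HOXB it was 0.08 (9 genes, exact p = 0.843). The order is in line with the hypothesis for 3 clusters, and HOXB argues against it as a rule for all 4, since 8 HOXB genes rose and HOXB13 alone fell. Levels differed too: 8 HOXA genes fell and none rose, 5 HOXC genes rose and 1 fell, and 5 HOXD genes rose and 3 fell.

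Joining the sites 2 by 2 was set beside all 35 splits of the 8 libraries into 4 and 4. For CZ and TZ against PZ and SV, 1 of 35 splits, the real one, gave as many genes (6, with 2 in the highest of the others). The replicate block left 0, as did leaving out either CZ or either TZ library. For CZ and SV against PZ and TZ, 2 of 35 gave as many (2, with 6 in the highest other), and for CZ and PZ against TZ and SV the count of 0 (edgeR; 2437 genes at p under 0.05, DESeq2 326) fixes the outcome at 35 of 35, with 6 in the highest other. All but 3 splits part the libraries of a site and so are unlike a join, and 3 are too few for a share under 0.05. IRX4 alone, picked after its values were seen, was lower in CZ than in PZ by -3.71 ± 0.17 and than in TZ by -3.69 on the log2 scale (adjusted p = 7.72e-08 and 2.61e-08), and differed by 0.02 between PZ and TZ (adjusted p = 0.991).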
